A study of Caenorhabditis elegans with 2 samples.

How the data were processed

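Whole Caenorhabditis elegans fed bacteria that make double-stranded RNA for imp-2 or for GFP were profiled on 2 Affymetrix arrays, 1 per group, from total RNA, per the labels. The groups were taken from the label text that names the RNA that was fed. The deposited values are intensities on a linear scale, 1 per probe set and array, between 0.0235 and 11334 on the array labelled imp-2 RNAi and between 0.0819 and 11100 on the array labelled GFP RNAi. They were already summarised over the probes of each set. The mean after trimming 2% at each end was the same on both arrays, at 150.04, as scaling of whole arrays to a common target gives. The summarisation, the background correction and the scaling method are not given in the sources used here, and neither are detection calls or the values of single probes. Strain, stage and culture conditions are likewise not given, and whether the arrays were processed on the same day is not known.

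Probe sets were named from the platform's annotation. Of the 22548 probe sets that are not controls, 20766 had 1 gene, 887 had several and 895 had none, and only those with 1 gene entered the gene-level results. Gene IDs were matched to the gene table of the WBcel235 assembly, used for names and for which genes are neighbours; 65 probe sets with 1 gene had an ID outside that table and kept the annotation's symbol, and 0 symbols changed. The array's own build is not given in the sources used here, so no coordinates are printed.

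Intensities were converted to log2. For a gene with several probe sets, the set with the highest mean log2 intensity over both arrays was used. Values under an array's median intensity over the probe sets that are not controls (35.3 and 30.1 on the arrays labelled imp-2 RNAi and GFP RNAi) were set to that median as a floor, so that a fold against such a value is a lower bound. Folds against values just above a floor, as for spe-4, dnj-7 and sss-1, rest on readings near that limit. The highest of the 32 controls for transcripts absent from the sample read 14.4 and 15.3, below both floors. A gene counted as expressed when its mean log2 intensity lay above the median of that mean over the probe sets that are not controls. Log2 ratios (imp-2 RNAi label over GFP RNAi label) were centred on the median of the expressed genes, a shift of 0.01. Genes were counted when they differed by at least 2-fold. With 1 array per group no p-value was computed, and the number of arrays limits the precision.

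A spread within this pair of arrays came from 2489 pairs of expressed probe sets of the same gene (1851 genes): the root mean square difference of their log2 ratios divided by the square root of 2 was 0.37. The planned standard deviation of the difference depends on the order of a pair, so the root mean square was used in its place. Of these pairs, 66.4% had the same sign. This covers disagreement between probe sets on the same arrays and holds nothing about the spread between cultures.

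The analysis used 33 gene lists fixed before the data were examined. For each, the median log2 ratio of its expressed members was set against 10000 random lists of the same size, matched on mean log2 intensity in 10 bins (seed 1). The number of random lists with a median at least as high describes these arrays only and is not a p-value. Under each alternative the random lists were drawn again, and a list is called inside or outside the random range against those. Some genes stand in several lists, such as nlp-29 and mup-4. Genes were named by a rule fixed at the same time: the 12 highest and 12 lowest ratios measured above the floor on both arrays, up to 5 bounds in each direction with the brighter array above its 75th percentile, every presenilin and IMPAS member with lin-12, glp-1, apl-1 and lrp-1, and up to 4 members of each list with the largest absolute log2 ratio. Of the named genes, 44 had several probe sets; among 48 other expressed sets, 7 had the opposite sign and 12 differed by at least 1 on the log2 scale, and these are given beside the genes. Probe sets whose suffix marks possible matches to several transcripts were kept and left out in an alternative. The split of the antimicrobial list by gene class and that of the sperm list into msp and other genes were made after the values were seen, and msp-36 and vit-5 were named then.

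The steps were tested on simulated data for the imp-2 RNAi against GFP RNAi comparison, over 8554 expressed genes with the noise of the probe set spread. All genes changed 8-fold were recovered past 2-fold, and 82.8% of those changed 2.83-fold. Among unchanged genes 24 were called higher and 22 lower. Both simulated arrays had the same baseline and no spread between cultures, so these counts give no error rate for the real calls. A list shifted by 0.3 gave a median of 0.24, and 5 of 40 unshifted lists fell outside the central 95% of random lists, where 2 would be the average. Of 920 further unshifted lists, drawn with the sizes of the gene classes in the closing section, 43 (4.67%) fell outside. The alternatives were no centring, quantile normalization, intensity-dependent centring by lowess (span 0.3), other filters and floors, an offset before the log, other fold thresholds, the mean over probe sets and the removal of probe sets that can match several transcripts. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.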

Results

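The series measured messenger RNA levels in whole Caenorhabditis elegans with Affymetrix arrays, on which each transcript is read by a set of short oligonucleotide probes. The nematodes were fed the Escherichia coli strain HT115, which makes double-stranded RNA that the animal takes up and that starts RNA interference (RNAi). In 1 sample the bacteria made double-stranded RNA for imp-2. In the other they made it for green fluorescent protein (GFP), the control. The gene imp-2 encodes a member of the IMPAS or signal peptide peptidase family, intramembrane aspartyl proteases related to the presenilins, and the series title names the regulation of presenilin genes as its subject. Each group holds 1 array, so no difference below has a replicate check, and no test of a difference between the groups was possible. The stage of the animals is not given in the sources used here. The source label also names a region of the mammalian brain beside the whole animal, which a nematode does not have.

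Each array gave 22625 probe set intensities, of which 77 were controls. The deposited values had the same overall level: the mean after trimming 2% at each end was 150.04 on both arrays. Log2 intensities correlated across the 22548 other probe sets with a Pearson r of 0.912 and a Spearman rho of 0.934; these are correlations across genes, which are not independent replicates. The 18 hybridisation controls had a median log2 ratio of −0.13 between the arrays. RNA integrity controls differed between the arrays in no common direction: the 3′ over 5′ ratio was 2.31 against 3.64 for actin and 1.12 against 1.37 for the Gapdh control on the array labelled imp-2 RNAi against the array labelled GFP RNAi, but 8.03 against 6.49 for the catalase control and 16.7 against 12.1 for ubiquitin. A total of 17118 genes had a probe set of their own, and 8553 of them counted as expressed.

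The first question was whether imp-2 itself was lower on the array labelled imp-2 RNAi, and its 2 probe sets gave ratios of opposite sign. The brighter one read 1754 under the imp-2 label and 2318 under the GFP label, which is 1.33-fold lower (log2 ratio −0.41). The other one, whose suffix marks possible matches to several transcripts, read 2517 under the imp-2 label and 510 under the GFP label, which is 4.90-fold higher (log2 ratio 2.29). The difference of 2.71 between the log2 ratios was the largest among 2489 pairs of expressed probe sets of the same gene, whose spread was 0.37. On the brighter set the drop was smaller than 2 such spreads. The target gene therefore does not settle which array received which RNA. Where the fed double-stranded RNA lies relative to the probes is not given in the sources used here, and a probe set inside the fed region would not measure the message alone. For this reason both arrays are named by their labels throughout, and every direction given here is a direction between labels.

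**Figure D1:**
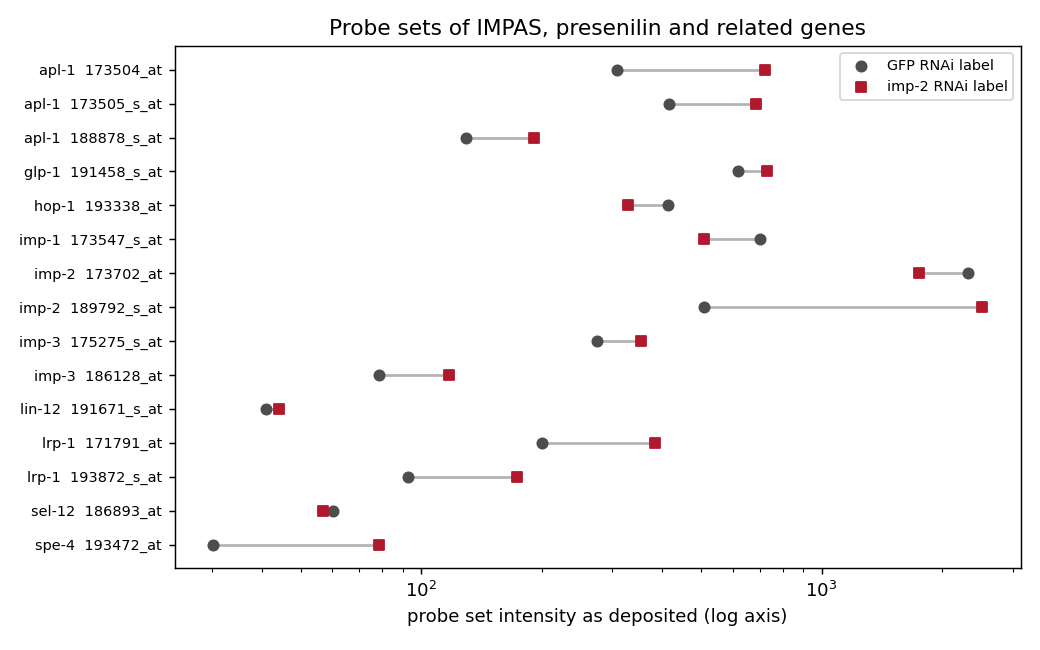
Intensity of each probe set of the presenilin and IMPAS genes and of lin-12, glp-1, apl-1 and lrp-1 on a log axis, as deposited, with 1 point per array (circle, GFP RNAi label; square, imp-2 RNAi label). The 2 imp-2 probe sets move in opposite directions, from 2318 to 1754 and from 510 to 2517.

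The relatives of imp-2 differed little between the labels, apart from spe-4. Presenilins are the catalytic subunits of gamma-secretase, which cleaves Notch receptors and related membrane proteins. The presenilin gene sel-12 had a log2 ratio of −0.09 and hop-1 of −0.34, and sel-12 was dim on both arrays (57 under the imp-2 label and 60.3 under the GFP label). The IMPAS genes imp-1 and imp-3 had log2 ratios of −0.47 and 0.35. The presenilin-related gene spe-4, which acts in sperm development, was 2.57-fold higher under the imp-2 label, although its value under the GFP label (30.2) lay just above the floor of that array (30.1). The median of the 6 presenilin and IMPAS genes was −0.22, inside the range of matched random lists, and it was 0.19 when each gene was the mean of its probe sets.

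Among gamma-secretase substrates and Notch pathway genes, 12 of 13 expressed members lay within 2-fold between the labels. The exception was sel-10, an F-box gene that acts in Notch turnover, which was 2.17-fold lower under the imp-2 label (log2 ratio −1.12), and its other probe set gave −1.06. The Notch pathway transcription factor lag-1 had a log2 ratio of −0.96 (−1.06 on its other probe set, past 2-fold lower) and the metalloprotease gene sup-17 one of −0.65. The Notch receptor genes lin-12 and glp-1 had log2 ratios of 0.10 and 0.23. The gene of the amyloid precursor protein homologue, apl-1, had a log2 ratio of 0.71, with 1.22 and 0.55 on its other probe sets. The median of this list was −0.26, inside the central 95% of random lists matched on brightness (−0.29 to 0.29), and below it with quantile normalization (−0.37), with intensity-dependent centring (−0.42) and over the 9 members above the 75th percentile of brightness (−0.31).

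Across the 8553 expressed genes, 831 were at least 2-fold higher under the imp-2 label, 194 were at least 2-fold lower and 7528 lay within 2-fold. At least 4-fold, 68 were higher and 17 lower. The calls therefore leaned to 1 side: 81.1% of them were higher under the imp-2 label, and the share was 71.2% after quantile normalization of the arrays. Without the filter on dim genes it was 56.9% (530 higher and 402 lower), with the centre at the ratio of genes under the floor on both arrays. In 139 of the higher and 32 of the lower genes the dimmer array lay under its floor, so that the fold is a lower bound. Second probe sets of the called genes mostly pointed the same way: 96.2% of them for higher genes and 67 of 77 for lower genes, with 51.0% and 20.8% past 2-fold themselves. The log2 ratio also depended on brightness, with a median of 0.24 in the dimmest of 10 equal bins of expressed genes and −0.09 in the brightest bin, where 23 genes were higher and 23 lower. The log2 ratio of the floors themselves was 0.23, and values raised to a floor are drawn toward it. Part of the rise in the dimmest bin may therefore come from the processing. The bins were not computed without the floor.

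The genes with the highest ratios included those of secreted defence peptides, an acid phosphatase and a lipid-binding protein. The array labelled imp-2 RNAi read 2393 for srlf-34 against 43.6 on the array labelled GFP RNAi, which is 54.5-fold higher, and Y41C4A.32 was 50.8-fold higher. After these came cnc-4, which encodes an antimicrobial caenacin peptide (11.6-fold), the acid phosphatase gene pho-6 (11.2-fold) and far-3, which encodes a fatty acid and retinol binding protein (9.67-fold). The value of pho-6 under the GFP label (32.1) lay just above the floor of that array (30.1). The others of the 12 highest lay between 6.61-fold and 7.78-fold: F13D12.3, scl-2, the beta-tubulin gene tbb-6, the calcium-binding calexcitin gene cex-1, F45E4.5, R07E3.1 and nlp-29. Genes under the floor on the array labelled GFP RNAi gave bounds of at least 14-fold for dbd-13, 9.21-fold for fipr-24, 8.16-fold for C45B2.2, 7.01-fold for warf-1 and 6.80-fold for oac-14.

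The genes with the lowest ratios were led by C-type lectin domain genes. Under the imp-2 label clec-223 was 10.7-fold lower (41.6 against 441), clec-222 was 10.4-fold lower, C48B4.12 was 9.86-fold lower and clec-197 was 8.92-fold lower. Of the brighter genes, Y57G11B.5 read 518 against 3344, which is 6.50-fold lower, W02D9.7 was 4.47-fold lower and K07A1.6 was 4.15-fold lower. The remaining genes among the 12 lowest were K03D3.5 (5.49-fold), the G protein-coupled receptor kinase gene grk-1 (4.59-fold), F59B2.12 (4.40-fold), fipr-16 (4.38-fold) and R11A8.1 (4.17-fold). The lectin genes clec-190 and clec-99 lay under the floor on the array labelled imp-2 RNAi and were at least 5.63-fold and 5.58-fold lower.

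**Figure D2:**
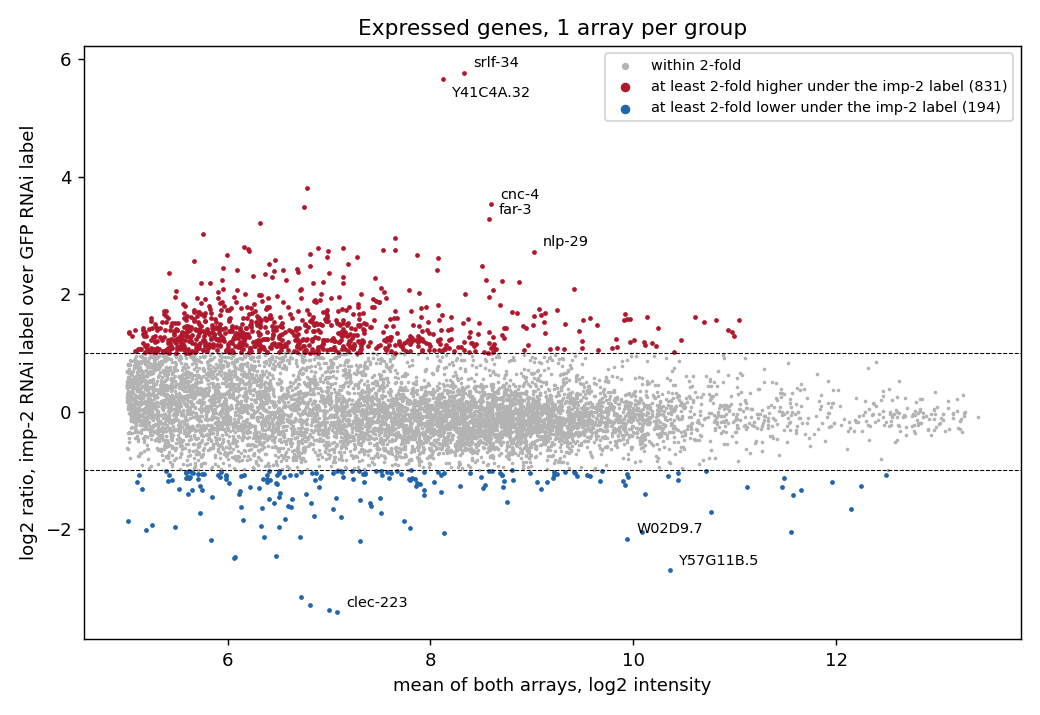
Centred log2 ratio of each expressed gene (imp-2 RNAi label over GFP RNAi label) against its mean log2 intensity on both arrays, 1 point per gene; dashed lines mark 2-fold. The 831 genes at least 2-fold higher outnumber the 194 at least 2-fold lower, and srlf-34 and Y41C4A.32 stand above the rest.

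Genes of the cuticle and of molting, the shedding of the old cuticle between larval stages, were higher under the imp-2 label as groups. Of 81 expressed cuticle collagen genes, 17 were at least 2-fold higher, 1 was lower and 63 lay within 2-fold; their median log2 ratio was 0.48, and 0 of 10000 matched random lists had a median as high. The collagen genes furthest from 0 were col-90 (at least 3.81-fold higher), col-104 (3.67-fold), dpy-5 (3.52-fold) and col-14 (3.39-fold). Of 30 molting and cuticle processing genes, 7 were higher and 1 was lower, with a median of 0.62 that 6 of 10000 random lists reached. In this list dpy-18, a prolyl 4-hydroxylase subunit that modifies collagens, was 3.14-fold higher, with log2 ratios of 3.07 and 2.80 on its other probe sets. The apical matrix gene noah-1 was 2.71-fold higher. The leucine-rich repeat genes sym-1 and pan-1 were 2.59-fold and 2.46-fold higher, although a second pan-1 probe set had a log2 ratio of 0.14. The megalin homologue lrp-1, an epidermal receptor needed for molting, was 1.90-fold higher, and its other probe set was 1.85-fold higher.

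Basement membrane genes stood with them. Of 10 expressed, 4 were at least 2-fold higher under the imp-2 label and none was at least 2-fold lower, with a median log2 ratio of 0.84 that 4 of 10000 random lists reached. The type IV collagen gene emb-9 was 3.01-fold higher (log2 ratio 1.59, but 0.56 on its other probe set), the papilin gene mig-6 was 2.86-fold higher, the laminin gene lam-3 was 2.68-fold higher and the nidogen gene nid-1 was 2.12-fold higher. The other mig-6 probe sets had log2 ratios of 1.08 and 0.60.

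Hedgehog-related and patched-related genes, many of them expressed in the epidermis, had a median log2 ratio of 0.36 between the labels, which 641 of 10000 random lists reached, and −0.21 over the members above the 75th percentile of brightness. Of 20 expressed, 4 were at least 2-fold higher under the imp-2 label: ptr-23 (2.77-fold, with 0.23, 1.06 and 0.97 as log2 ratios of its other probe sets), grl-15 (at least 2.64-fold), ptr-24 (2.49-fold) and ptr-8 (2.48-fold). Of 12 epidermis markers other than collagens, 2 were higher under the imp-2 label, let-805 (2.39-fold) and mup-4 (2.30-fold). The marker median was 0.46, which 140 random lists reached, but it was 0.25 and 0.22 and inside the random range after quantile normalization and intensity-dependent centring, and −0.19 over the 5 brightest members. For the cell junction genes ajm-1 (0.84) and dlg-1 (−0.78) the probe sets disagreed in sign. The other expressed ajm-1 sets had log2 ratios of −0.57, −0.69, 0.60 and 0.92, and the other dlg-1 set had 0.54.

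Antimicrobial and innate immune genes spread widely in both directions between the labels. Of 103 expressed, 31 were at least 2-fold higher and 17 at least 2-fold lower under the imp-2 label, and the median log2 ratio was 0.37, which 0 of 10000 random lists reached. By gene class, the 54 C-type lectin domain (clec) genes held 11 higher and 12 lower and had a median of −0.08. In the smaller classes, 3 of 5 cnc, 4 of 6 nlp, 3 of 5 lys, 3 of 6 irg and 2 of 6 dod genes of this list were higher and none of them was lower. The 5 fipr genes held 2 higher and 2 lower, the 11 spp genes 2 higher and 1 lower, the 2 ilys genes 1 of each, and of the 2 abf genes 1 was lower. Differences between the classes were not tested. Besides cnc-4 and nlp-29, the peptide genes nlp-30 and nlp-31 were 6.15-fold and 4.19-fold higher. The gene nlp-25, which is in the neuropeptide list and not in this one, was at least 6.32-fold higher. The probe sets of nlp-29, nlp-30 and nlp-31 carry a suffix that marks possible matches to several transcripts, so these neighbouring paralogs are not told apart with certainty. Without such probe sets the median of the list was 0.09 over 64 genes, inside the random range, while it was 0.22 after quantile normalization and 0.64 over the 42 members above the 75th percentile of brightness.

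Genes of the endoplasmic reticulum (ER) stress response were higher under the imp-2 label as a group. Of 23 expressed, 5 were at least 2-fold higher and none was at least 2-fold lower, with a median log2 ratio of 0.40 that 0 of 10000 random lists reached. The choline kinase gene ckb-2 was 5.55-fold higher, the co-chaperone gene dnj-7 was 3.34-fold higher, the chaperone gene hsp-4 (the BiP homologue) was 2.45-fold higher (3199 against 1294) and the ER stress kinase gene pek-1 was 2.40-fold higher. The median was 0.21 after quantile normalization and 0.24 after intensity-dependent centring. It was 0.08 over 12 genes without probe sets that can match several transcripts and 0.15 over the 19 brightest members, both inside the random range. The abu and pqn genes, listed for a prion-like domain, had a median of 0.00 (−0.13 after quantile normalization). Of 36, 1 was higher (abu-14, 2.02-fold) and 3 were lower (pqn-68, 2.14-fold, pqn-84, at least 2.12-fold, and pqn-21, 2.04-fold). Other probe sets had log2 ratios of 0.19 for abu-14 and 0.25 for pqn-21.

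Of 15 expressed cytosolic heat shock genes, 4 were at least 2-fold higher under the imp-2 label and 1 was lower, with a median log2 ratio of 0.43 that 12 of 10000 random lists reached. The inducible chaperone gene hsp-70 was 3.37-fold higher, and the small heat shock protein genes hsp-16.2 and hsp-12.3 were 2.54-fold and 2.34-fold higher. The lower one was hsf-1, which encodes the heat shock transcription factor (2.76-fold lower). Another hsf-1 probe set had a log2 ratio of −0.88.

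Genes of the cytochrome P450 and UDP-glucuronosyltransferase classes, which act in detoxification, were higher under the imp-2 label as a group. Of 58 expressed, 13 were at least 2-fold higher and none was at least 2-fold lower, with a median log2 ratio of 0.42 that 18 of 10000 random lists reached. The median was 0.24 after quantile normalization and 0.23 after intensity-dependent centring, both above the central 95% of random lists drawn under those settings. Examples were cyp-13A5 (4.83-fold higher), ugt-8 (3.42-fold), cyp-43A1 (3.18-fold) and ugt-23 (3.12-fold). Glutathione transferase and antioxidant genes did not stand apart: 28 of 32 lay within 2-fold and 4 were higher, led by the catalase gene ctl-2 (2.78-fold), with gst-15 (at least 2.43-fold), gsto-1 (at least 2.31-fold) and the superoxide dismutase gene sod-4 (2.24-fold) after it. The median of that list was 0.21, which 496 random lists reached and which lay inside the random range, and it was 0.07 after quantile normalization.

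Lipid metabolism genes and cathepsin and aspartyl proteases were higher under the imp-2 label as groups, and so were the markers of the intestine, with a median log2 ratio of 0.73. Of 68 expressed genes of fatty acid metabolism and lipid binding, 17 were at least 2-fold higher and 2 lower, with a median log2 ratio of 0.31 that 1 of 10000 random lists reached. Besides far-3, the desaturase gene fat-5 was 5.70-fold higher and the acyl-CoA synthetase genes acs-6 and acs-22 were 4.0-fold and 3.66-fold higher. Of 18 cathepsin and aspartyl protease genes, 6 were higher and 1 was lower, with a median of 0.64 that 0 of 10000 random lists reached. The cathepsin B-like gene cpr-6 was 2.97-fold higher, the cathepsin D-like gene asp-3 was 2.96-fold higher and the cathepsin L gene cpl-1 was 2.69-fold higher, with a log2 ratio of 0.36 on another, dimmer cpl-1 probe set. The aspartyl protease gene asp-13 was 2.91-fold lower. Sterol and steroid hormone genes had a median of 0.16, which turned to −0.06 and −0.01 after quantile normalization and intensity-dependent centring; nhr-8 was 2.04-fold higher and the 10 others lay within 2-fold, among them ncr-1 (0.92), ncr-2 (0.85) and nstp-4 (−0.90).

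Of the cell type markers, those of the intestine were furthest from 0. Of 12 expressed, 4 were at least 2-fold higher under the imp-2 label and none was at least 2-fold lower, with a median log2 ratio of 0.73 that 83 of 10000 random lists reached. The metallothionein gene mtl-1 was at least 5.35-fold higher, the gut esterase gene ges-1 was 2.72-fold higher, the transcription factor gene elt-7 was at least 2.24-fold higher and the intermediate filament gene ifb-2 was 2.15-fold higher. The 5 vitellogenin genes, which encode yolk proteins made in the adult intestine, lay within 2-fold, with log2 ratios of 0.74 for vit-6, 0.63 for vit-2, 0.51 for vit-1 and −0.30 for vit-4, while vit-5 lay at 0.00. Another vit-6 set had 0.28, and the other vit-4 sets had −0.29 and, on a dimmer set, −1.25. Their median of 0.51 was reached by 31 random lists. Body wall muscle markers had a median of 0.03 (−0.02 without probe sets that can match several transcripts), with 1 of 24 higher (tni-1, 2.17-fold) and the next furthest at 0.93 (tni-3), −0.80 (deb-1) and −0.65 (unc-89); another deb-1 probe set had a log2 ratio of 0.09, and the other expressed unc-89 sets had −0.42 and 0.32. Pharynx markers had a median of −0.22, with 1 of 15 lower (phat-3, 2.16-fold) and phat-6, phat-4 and phat-8 at −0.68, −0.55 and −0.52. Neuron markers had a median of −0.03, with unc-64 the 1 of 17 that was higher (2.16-fold), while ric-4 (−0.91), unc-119 (−0.78) and snt-1 (−0.49, with the array labelled imp-2 RNAi under its floor) lay within 2-fold. The neuron median was −0.26 after quantile normalization, −0.29 after intensity-dependent centring and −0.25 without probe sets that can match several transcripts. The medians of these last 3 marker lists lay inside the random range, but that of the pharynx list was −0.41 and below it over the 10 genes left without probe sets that can match several transcripts.

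**Figure D3:**
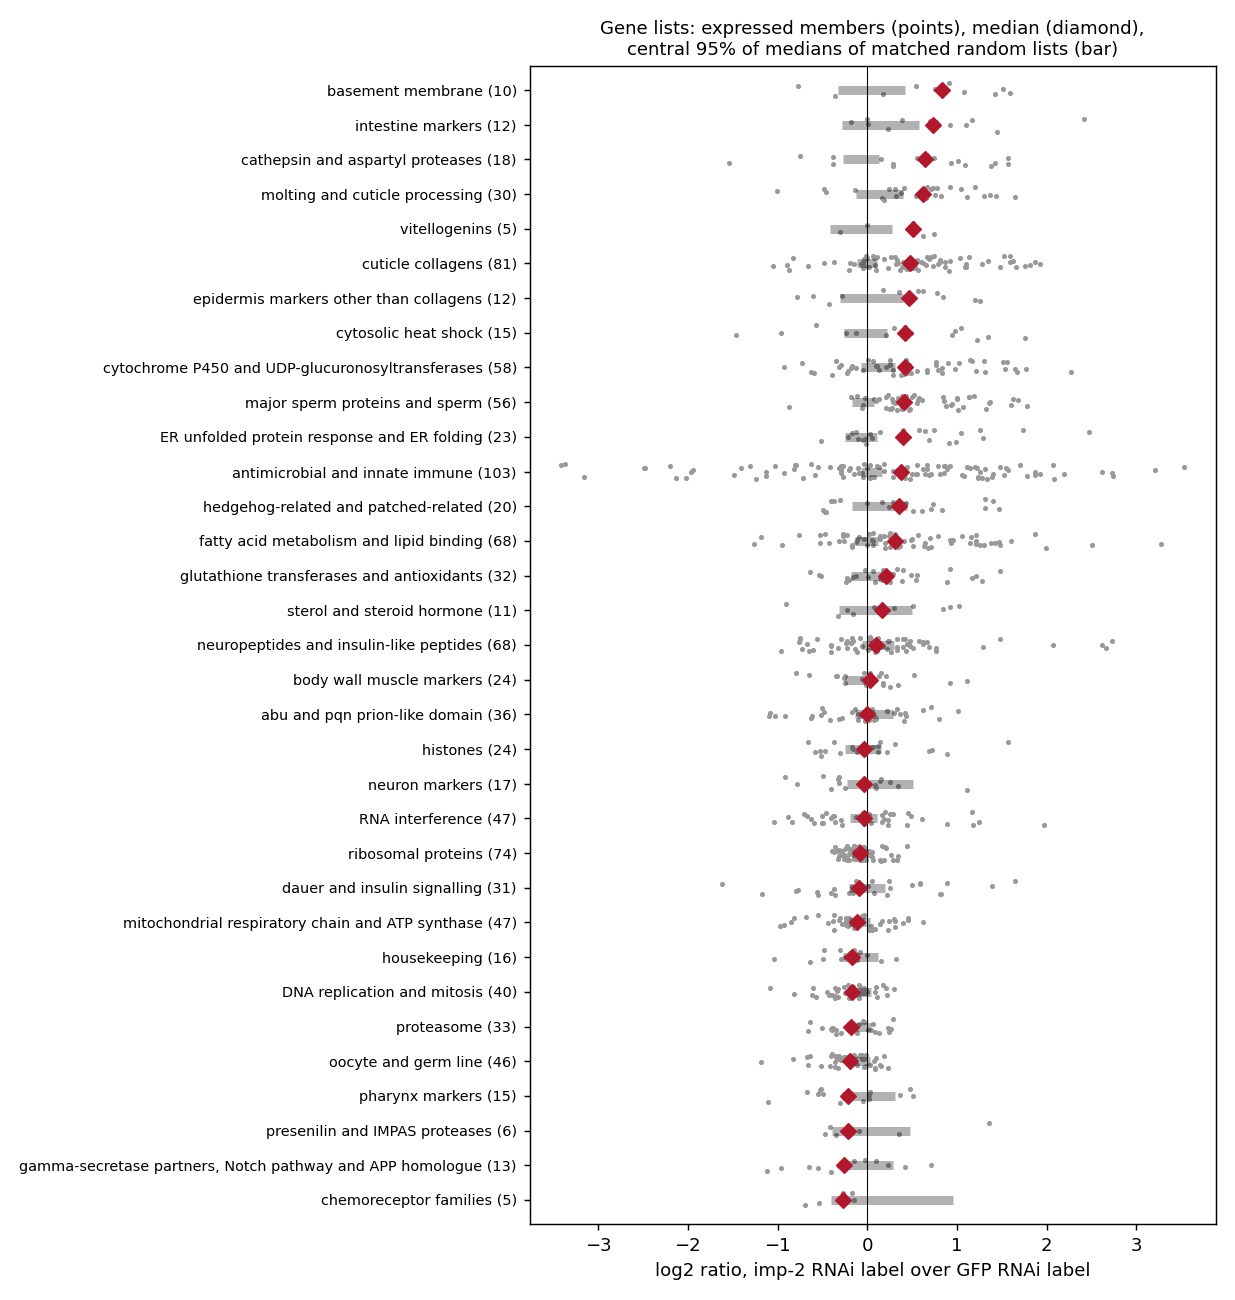
Centred log2 ratios (imp-2 RNAi label over GFP RNAi label) of the expressed members of each gene list, 1 point per gene, with the list median as a diamond and the central 95% of medians of 10000 random lists matched on brightness as a bar; the number of members stands in parentheses. Basement membrane (0.84) and intestine markers (0.73) have the highest medians, and 13 lists lie outside the bar, all above it.

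Sperm genes were higher under the imp-2 label as a group, while the medians of oocyte and cell division genes lay below 0. Of 56 expressed major sperm protein and other sperm genes, 12 were at least 2-fold higher and none was at least 2-fold lower, with a median log2 ratio of 0.41 that 0 of 10000 random lists reached. The 12 were outside the major sperm protein (msp) class, whose 23 genes lay within 2-fold with a median of 0.29 and a highest value of 0.84 (msp-36). The 33 other sperm genes had a median of 0.88. The list median was 1.02 over the 16 genes left without probe sets that can match several transcripts. Those furthest from 0 were sss-2 (3.43-fold higher), sss-1 (3.21-fold), spe-15 (at least 3.09-fold) and spe-46 (3.03-fold). Of 46 oocyte and germ line genes, 1 was lower (mex-1, 2.28-fold) and 45 lay within 2-fold, among them puf-7 (−0.83), gld-1 (−0.67) and mex-3 (−0.66); the median was −0.19, near the lower end of the random range of −0.20 to 0.03. Against random lists drawn under the same setting it lay below the central 95% with quantile normalization (−0.15), over the members above the 75th percentile of brightness (−0.12) and as the mean over probe sets (−0.19). DNA replication and mitosis genes had a median of −0.17, inside the random range, with 1 of 40 lower (the spindle gene tpxl-1, 2.13-fold) and cdk-1 (−0.82), cye-1 (−0.62) and orc-2 (−0.60) next. Another expressed tpxl-1 probe set had a log2 ratio of −0.66. Histone genes had a median of −0.03, which turned to 0.01 after intensity-dependent centring and was 0.49, above the random range, over the 6 genes left without probe sets that can match several transcripts, with 1 of 24 higher (the histone H3 gene his-70, 2.96-fold). Others furthest from 0 were his-71 (0.88, a bound), his-37 (0.72) and his-24 (0.69).

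Genes of the RNA interference machinery had a median near 0 between the labels that depended on the probe sets used. The median log2 ratio of 47 expressed members was −0.04, inside the random range, and its sign turned after quantile normalization (0.02). Over the 26 genes left without probe sets that can match several transcripts it was −0.34, below the random range. The 4 genes at least 2-fold higher under the imp-2 label were alg-3 (3.92-fold) and alg-4 (2.26-fold), Argonaute genes of the sperm-producing germ line, together with drh-2 (2.37-fold) and rrf-2 (2.25-fold). Another expressed alg-4 probe set had a log2 ratio of 0.89. Of 31 dauer and insulin signalling genes, 2 were higher, daf-22 (3.14-fold), a thiolase gene of peroxisomal fatty acid oxidation, and dct-11 (at least 2.63-fold). The 2 lower ones were pdk-1 (3.08-fold) and daf-5 (2.25-fold), although other expressed probe sets had log2 ratios of −0.65 for pdk-1 and −0.09 for daf-5. The median of this list was −0.09, and 0.03 as the mean over probe sets. Neuropeptide and insulin-like peptide genes had a median of 0.10 over 68 genes, which turned to −0.12 after quantile normalization and was 0.44, above the random range, over the 14 members above the 75th percentile of brightness. The 6 that were higher were led by nlp-29, nlp-25, nlp-30 and nlp-31, named above.

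Genes of basic cell functions mostly lay within 2-fold between the labels. All 74 expressed ribosomal protein genes lay within 2-fold, with a median log2 ratio of −0.08 that turned to 0.01 after quantile normalization, and the furthest were rpl-23A.1 (0.44), rps-28 (−0.39), rps-29 (−0.37) and rpl-30 (−0.35). All 33 proteasome genes lay within 2-fold (median −0.18), with pas-7 (−0.66), pas-2 (−0.64), pbs-1 (−0.50) and pas-5 (−0.41) furthest. All 47 genes of the mitochondrial respiratory chain and ATP synthase did so too (median −0.11, and 0.02 above the 75th percentile of brightness), with cox-18 (−0.98), cox-15 (−0.93), sdha-2 (−0.85) and sdha-1 (−0.82) furthest. Of 16 housekeeping genes, 1 was lower under the imp-2 label (ama-1, which encodes the largest subunit of RNA polymerase II, 2.06-fold), and rpb-2 (−0.64), tbp-1 (−0.49) and pmp-3 (−0.48) followed; the median was −0.17. Of 1126 measured chemoreceptor genes, 5 counted as expressed and all 5 lay within 2-fold, with a median of −0.27 (−0.47 after quantile normalization, −0.44 after intensity-dependent centring and −0.42 with no floor); sri-40 (−0.69) and srv-1 (−0.53) were furthest from 0. The medians of these 5 lists lay inside the random range.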

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

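The tests of explanations in this part were chosen after the results they bear on had been seen. Ratios past 2-fold also occurred in probe sets that no comparison above used. Of 597 expressed probe sets annotated to no gene or to several, 81 (13.6%) were at least 2-fold higher under the imp-2 label. A further 28 (4.69%) were at least 2-fold lower, and the log2 ratios ran from −2.51 to 3.43. Among the expressed genes these shares were 9.72% and 2.27%. Whether the difference in shares reflects more than matches to several transcripts was not tested.

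The 2 probe sets of imp-2 moved apart by 2.71 on the log2 scale. A related transcript matched by the set that was higher is argued against for imp-1 and imp-3, whose highest log2 ratio was 0.57 against 2.29 for that set. Fed double-stranded RNA read by 1 of the sets is a possible explanation of the 2.71, but the fed region and the probe positions are not given in the sources used here, so it cannot be told apart from other causes. Exchanged labels cannot be excluded either: the brighter set had a log2 ratio of −0.41, a drop smaller than 2 spreads of 0.37, while the other set was higher. A response of the imp-2 message to the treatment stays open and untested.

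More genes were higher than lower under the imp-2 label. A brightness-dependent difference in scale is argued against as the whole cause, because after intensity-dependent centring 72.6% of the calls were still higher (Wilson 95% interval over genes 69.6% to 75.4%, which treats genes as independent), although the share had been 81.1%. An equal rise of all somatic tissues, as a lower share of germ line alone could give, is also argued against as the whole cause. After that centring the medians of 5 somatic marker lists spanned 0.87, from −0.29 for neurons to 0.58 for the intestine, and 11 of 10000 shuffles of the genes among the lists gave a span as wide. These shuffles treat genes as independent. Embryos also hold cells of these tissues, so a lower share of embryos need not raise the lists alike. The span cannot decide on that cause. A lower share of germ line as a part of the cause also stays open, and the oocyte and germ line list had a median of −0.19. A difference in stage or culture between the samples and the fed RNA itself stay open, since with 1 array per group they coincide with the labels.

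Sperm genes were higher under the imp-2 label. The median of the sperm list lay 0.61 above that of the oocyte and germ line list (bootstrap 95% interval over genes 0.48 to 0.82). That interval treats genes as independent and holds nothing about the spread between samples. Cross-matching within the major sperm protein family is argued against for the other sperm genes, whose median was 1.06 over the 15 left without probe sets that can match several transcripts, against a random range of −0.29 to 0.50, but it stays open for the 23 genes of that family (median 0.29), of which 1 has an expressed probe set without that mark. Younger animals under the imp-2 label, still making sperm, could give such a pattern, and cannot be told apart here: the vitellogenins, made in adults, had a median of 0.51 with an interval over 5 genes from −0.30 to 0.74. The limits of that interval are the values of vit-4 and vit-6, the lowest and the highest, so it could not decide. The median lay above 0, where younger animals would give lower vitellogenins, while vit-4 went the other way. An effect of the fed RNA on the germ line stays open and untested.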

How the results depend on the processing

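The 2 alternatives on the imp-2 probe sets were chosen after seeing the data; the others were fixed before the data were examined. The imp-2 log2 ratio lay between −0.41 and −0.34 under no centring, quantile normalization, intensity-dependent centring and no floor, but turned to 2.29 with its other probe set and to 0.95 as the mean over both, so the direction of imp-2 rests on the choice of probe set. The counts of genes at least 2-fold higher and lower (831 and 194) stayed within 1.5 times under no centring (847 and 184), quantile normalization (639 and 259), intensity-dependent centring (665 and 251), a floor at the 25th percentile or none (902 and 219), an offset (741 and 162), the mean over probe sets (780 and 138) and the removal of sets that can match several transcripts (581 and 148). They moved by more with the filter on dim genes. Without it 530 were higher and 402 lower, 56.9% of the calls higher; 46.6% of the 17118 genes lay under the floor on both arrays, the median ratio was that of the floors, and centring shifted all ratios by 0.23 in place of 0.01. Over genes above the 75th percentile they were 239 and 51, as fewer genes enter. They were 1628 and 821 at 1.5-fold and 195 and 38 at 3-fold, by construction. The spread of 0.37 was 0.33 for bright genes and 0.39 with intensity-dependent centring. Of the 13 lists outside the random range, 6 stayed outside under each of the 7 alternatives that left 5 or more genes. Of the 91 alternative medians of the 13 lists, 3 rested on under 5 genes and were not compared, and 75 of the other 88 were outside again; of the 20 lists inside it, 6 lay outside under at least 1 alternative. Epidermis markers turned to −0.19 above the 75th percentile, where 5 members were left. Without the filter on dim genes several list medians were 0, the value of genes under the floor on both arrays. Among them were cuticle collagens, molting and cuticle processing, and cytochrome P450 and UDP-glucuronosyltransferases. So were antimicrobial and innate immune genes, fatty acid metabolism and lipid binding, and epidermis markers. These lists, outside the random range in the main analysis, lay inside it there. No paired analysis was possible because each group has 1 array. Signal over background limits the dim genes, which were left out, and the bounds.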

Other observations

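The gene classes here lie mostly outside the fixed lists and were looked up after the values were seen, among 184 classes with 5 or more expressed members; 14 lay above and 10 below the central 95% of matched random lists, 24 of 184 in all. Of lists of unchanged genes on simulated arrays, 5 of 40 (12.5%) and, with the sizes of these classes, 43 of 920 (4.67%) fell outside; the simulated genes vary independently, which members of a class need not do. Transthyretin-like (ttr) genes, which encode small secreted proteins, were the clearest: 13 of 33 were at least 2-fold higher under the imp-2 label and none was at least 2-fold lower, with a median log2 ratio of 0.57. Galectin (lec) genes had a median of 0.51, with 5 of 11 higher. The ctsa genes, related to the lysosomal carboxypeptidase cathepsin A, had a median of 0.81, with 3 of 6 higher. The small class dbd had a median of 1.19 with 4 of 6 higher, and dbd-13 is among the named bounds. These directions held under no centring, quantile normalization and intensity-dependent centring. The classes described here and below are examples from the 24. Among those left out, nsph had a median of 1.23 over 5 genes and scl one of −0.60 over 8 genes.

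On the lower side, all 6 par genes, which set up cell polarity in the embryo, lay below 0 under the imp-2 label with a median log2 ratio of −0.87, and none was past 2-fold. All 8 nucleolar nol genes lay below 0, with a median of −0.47. The 7 subunit genes of the cytosolic chaperonin (cct) had a median of −0.37, just below the random range of −0.36 to 0.28. The 33 mitochondrial ribosomal protein (mrpl) genes had one of −0.29, with 3 lower, against a random range of −0.25 to 0.07. These signs also held under the other scalings.

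Whether the genes higher under the imp-2 label lie next to each other on the chromosomes was asked with a bound written before the result was seen. Among 821 such genes with a place in the gene order, 34 adjacent pairs joined genes of different classes or clones. The 1000 random sets matched on brightness had a median of 32 and an upper end of the central 95% of 44, so the bound was not passed. Leaving out pairs named after the same clone also removes neighbours that a regional change would join, so this count cannot decide on such a change. With pairs of the same class or clone included there were 61 pairs, above the highest random set (60), so for the higher genes the excess came with pairs of related names, such as nlp-29, nlp-30 and nlp-31. The lower genes gave 12 pairs against a highest random set of 9, and 5 pairs of different classes or clones, at the upper end of the central 95% (5) and above the median of 2, so the part of unrelated names stays open there.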
